A study of Pseudomonas aeruginosa PAO1 with 3 samples.

How the data were processed

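Total RNA of P. aeruginosa PAO1 from 10 ml cultures harvested at an optical density of 0.4 to 0.6 was labelled with biotin from about 10 µg and hybridised to an Affymetrix array, per the labels' protocols. The deposited values are the authors' MAS5 signal intensities, on a linear scale, 1 value per probe set and array; MAS5 is named in the submitters' processing notes, without a version. From the values, each array had been scaled to a near-equal mean (500.68, 500.9 and 500.8 after leaving out the lowest and highest 2% of probe sets), and no detection calls were used here. Such scaling fixes the mean of all probe sets, so that a change shared by most genes cannot be seen. The table held 3 arrays, 1 of L-Glu and 2 of L-Glu plus D-Arg, grouped by the sample descriptions.

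Of 5896 probe sets, 5545 carry a PAO1 locus tag, 199 are intergenic, 117 report genes of other strains, 18 report tRNA, 3 rRNA, and 14 are controls. Only PAO1 gene probe sets entered the tests. Genes were named through their locus tags in a RefSeq gene table (assembly ASM676v1), which held 5504 of the 5545; the table gave names, the order of genes and coding lengths, and no coordinates are printed since no build is stated for the array. In the platform annotation 5500 probe sets had 1 gene symbol and 396 had several or none; among tested genes 70 were read by probe sets that can match several targets, which leaves near-identical copies uncertain. No aligner or build applies to these values.

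Signals were taken to log2 without an offset and without further normalization. The 25% of genes with the lowest mean log2 signal were left out (1387 genes, below a signal of 82.0), which left 4158. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend; two-sided; Benjamini-Hochberg adjustment over tested genes; adjusted p under 0.05). The design has 1 residual degree of freedom, which comes from the D-Arg arrays alone, so the lone L-Glu array is assumed to vary like them, and the prior degrees of freedom came out as infinite. Genes below the highest other-strain signal on the L-Glu array or on all D-Arg arrays are given a lower bound for the fold: the mean of the bright group over the dim group's values raised to that background, from means of log2 signals. Counts by size asked for at least 2-fold on both D-Arg arrays; they were set beside 100 simulations of unchanged genes with the spread of the D-Arg arrays.

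Gene lists (25, with 23 of at least 3 tested genes) were fixed by locus tag before the data were examined, as were the tests and the alternatives except where stated: D-arginine dehydrogenation, other D-amino acid catabolism, arginine and ornithine uptake, arginine succinyltransferase, transaminase and guanidinobutyrate, and arginine deiminase pathways, agmatine, putrescine and polyamine catabolism, polyamine synthesis, arginine biosynthesis, glutamate uptake and use, nitrogen assimilation, tricarboxylic acid cycle, pyoverdine, pyochelin, haem uptake, denitrification, quorum sensing, phenazine synthesis, flagellum, type III secretion, chaperones, peroxide defence, lipid A modification, multidrug efflux and ribosomal proteins. They were tested with camera at a preset correlation of 0.01, adjusted over the lists. Fold changes of neighbouring tested genes had a rank correlation of 0.403. Camera p-values of lists made of neighbouring genes are thus likely too small. With an estimated correlation, which here rests on 1 residual degree of freedom, and with fry, 0 lists were called. Lists of low-oxygen and sulphur-supply genes were written later, from genes outside the largest differences already seen. Named genes were, among genes at least 2-fold changed the same way on both D-Arg arrays, the 10 with the highest and the 10 with the lowest log2 fold change, all members of D-arginine dehydrogenation, and up to 3 members with the largest absolute change in each other list; a few others are named where a count or list calls for them.

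The tests were checked on simulated data with 200 of 4158 genes changed. Where all genes of like signal shared 1 spread, 78% of genes changed by 2 and 100% of genes changed by 3 on the log2 scale were recovered, with 4.81% false calls. With a spread that differed between genes, 9% and 75% were recovered, with 2.33% false calls. The prior degrees of freedom came out as infinite in the first simulation and as 4.08 in the second. Neither simulation joined infinite ones with a spread that differed between genes. These shares of false calls therefore need not hold for the real calls. Alternatives were no filter, leaving out the dimmest 40%, an offset of 80.1 before log2, quantile normalization, median centring, other variance models, a 3-fold rule, and leaving out either D-Arg array. Runs of neighbouring genes were sought with windows of 6 tested genes in locus-tag order against 1000 random orders.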

Results

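Pseudomonas aeruginosa PAO1, the sequenced laboratory strain of this opportunistic pathogen, was grown at 37 °C with shaking at 300 rpm. The minimal medium held 20 mM L-glutamate (L-Glu), alone or together with 20 mM D-arginine (D-Arg), the mirror image of the L-arginine found in proteins. This follows the sample descriptions and the growth protocol; the series title instead names either L-glutamate or D-arginine. Transcript levels were read on an Affymetrix oligonucleotide array on which 5545 probe sets each report a PAO1 gene. There was 1 array of the L-Glu culture and there were 2 arrays of L-Glu plus D-Arg, called D-Arg replicates 1 and 2 here. The median signal of PAO1 genes was 230.9 on the L-Glu array, 222.7 on D-Arg replicate 1 and 217.8 on D-Arg replicate 2. The brightest of 117 probe sets for genes of other strains, taken as the background, had signals of 33.1, 46.2 and 37.8 on these arrays. On them 91.2%, 88.0% and 88.3% of PAO1 genes lay above that background. The number of arrays, with a lone L-Glu array, limits the precision of every value below.

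The comparison asks which genes respond when D-Arg is added to a culture growing on L-Glu. With D-Arg, all 4 genes of D-arginine dehydrogenation, all 6 of the arginine succinyltransferase pathway and 10 of 11 for the siderophore pyochelin rose. In the run PA1970 to PA1991, which holds genes for ethanol oxidation and its quinone cofactor and was singled out after the values were seen, 17 of 20 genes rose. Genes of the type III secretion system, a needle-like machine that injects toxins into host cells, fell (18 of 25 tested). Of the 10 genes with the largest increase, 8 lay in the ethanol oxidation run, and the other 2 were dauA and dauB of D-arginine dehydrogenation. Of the 10 genes with the largest decrease, 7 belonged to the type III secretion list. Another, PA3842, encodes the chaperone of a type III toxin but is not in that list. Among 4158 tested genes, 121 rose and 57 fell (limma with an intensity trend, adjusted p under 0.05), and 395 had an unadjusted p under 0.05. Of the 178 called genes, 176 had the same sign on both D-Arg arrays, dctA and arcC being the exceptions, and 11 were not 2-fold changed on both. The median gene shifted by -0.13 on the log2 scale, the median standard error of a log2 fold change was 0.54, and the smallest change called was 1.63.

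These counts rest on how the arrays are scaled and how the spread between them is modelled. With each array centred on its median 30 genes rose and 3 fell, all 33 of them among the 178, so that 90.9% of the calls were increases against 68%. With quantile normalization 11 rose and 0 fell in limma, with 289 genes at an unadjusted p under 0.05. The 178 calls take the spread as the same for all genes of like signal. Yet 105 genes, 17 of them among the 178, differed between the D-Arg arrays by more than 3 standard deviations of that spread. A normal spread gives 11.2, so that p-values of such genes are too small. Those of all other called genes rest on the same assumed spread and not on their own. With the same infinite prior degrees of freedom, setting either D-Arg array against the other 2 arrays called more genes than the real grouping, as given below. By size alone, 158 genes were at least 2-fold higher on both D-Arg arrays than on the L-Glu array and 118 at least 2-fold lower. In 100 simulations without any effect, where the shared L-Glu array alone makes both ratios move together, the means were 99.8 (range 78 to 119) and 99.5 (range 73 to 123). The correlation of both ratios across tested genes, which are not independent replicates, was 0.646, against 0.499 simulated (0.46 to 0.53), and their covariance was 0.471 against 0.259 (0.229 to 0.295). Both ratios had the same sign in 2583 genes, fewer than in any simulation (mean 2770, range 2710 to 2840). The simulations thus do not match the spread of these data, which limits them as a yardstick for the counts of 158 and 118.

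**Figure D1:**
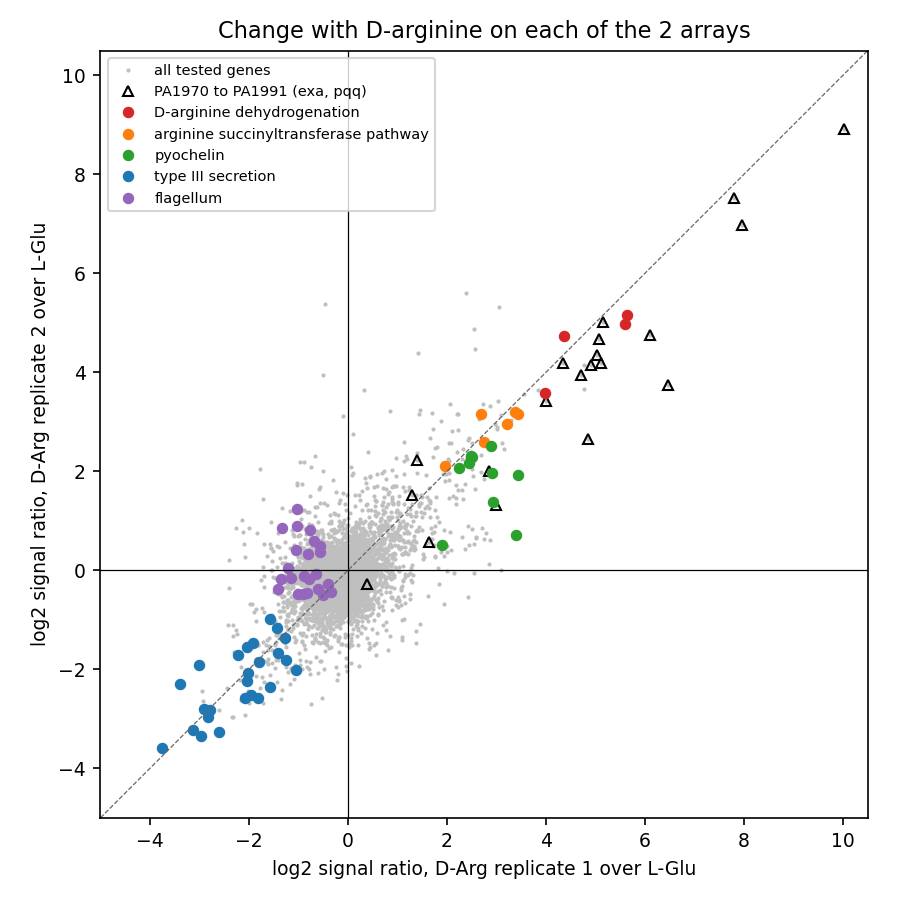
Log2 signal ratio to the L-Glu array on D-Arg replicate 1 (horizontal axis) and replicate 2 (vertical axis) for each of 4158 tested genes, with gene lists in colour, genes PA1970 to PA1991 as triangles and the line of equal ratios dashed. The D-arginine dehydrogenation, arginine succinyltransferase, pyochelin and PA1970 to PA1991 genes lie mostly near the line at upper right, the type III secretion genes at lower left, and most flagellum genes above the line, with medians of -0.82 on replicate 1 and -0.11 on replicate 2.

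All 4 genes of the D-arginine dehydrogenation locus rose, with a median log2 fold change of 4.92. The signal of dauA (PA3863), which encodes the dehydrogenase that turns D-arginine into its keto acid, went from 81.2 without D-Arg to 3247 ± 970 (SD, n = 2), a log2 fold change of 5.29 ± 0.53 (SE). The signal of dauB (PA3862), whose product reduces that keto acid to L-arginine, went from 215.4 to 9209 ± 2108 (SD, n = 2), a log2 fold change of 5.40 ± 0.53 (SE). The regulator gene dauR (PA3864) rose by 3.79 and the neighbouring PA3865, a predicted amino acid binding protein, by 4.55 on the log2 scale. The adjusted p of dauA was 1.15e-20, and 0.0112 with median centring and 0.0422 with quantile normalization. That of dauB was 3.37e-21, 0.0106 and 0.0121. All 4 genes were called with median centring and 3 with quantile normalization, and all 4 when p was adjusted over the list alone. As a set they stood above the other genes in camera (adjusted p = 2.22e-35, and adjusted p = 0.504 with an estimated correlation). The smaller value takes these 4 neighbouring genes as nearly independent and is likely too small, as for other lists of neighbours below.

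The arginine succinyltransferase pathway, the main aerobic route from L-arginine to glutamate, also rose in all 6 of its genes, with a median log2 fold change of 3.01. The largest changes were in aruD (PA0898; 284.1 to 2805 ± 397, SD, n = 2; log2 fold change 3.30 ± 0.53, SE; adjusted p = 5.67e-08), aruG (PA0897; 3.29) and aruB (PA0899; 3.09). The list was called by camera (adjusted p = 6.04e-20, and adjusted p = 0.504 with an estimated correlation). All 6 genes passed when adjusted over the list alone, 3 with median centring and 0 with quantile normalization. The arginine and ornithine uptake list holds the aot transporter and the regulator gene argR. Of these argR (PA0893) rose by 1.63 on the log2 scale (715.4 to 2232 ± 329, SD, n = 2; adjusted p = 0.0452). The other 5 genes did not pass, with aotQ at 1.53 and aotP at 1.51. The list median was 1.45, all 6 genes passed when adjusted over the list alone, 0 passed with median centring, and camera gave an adjusted p of 1.09e-05 (adjusted p = 0.713 with an estimated correlation).

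Other routes of arginine use, and lists related to them, moved in single genes. In the transaminase and guanidinobutyrate list (median 0.27, adjusted p = 0.0992, from camera here and for the lists that follow) the guanidinobutyrase gene gbuA rose by 3.53 (66.7 to 397.4 and 1488 on the D-Arg arrays). The median of that list was 0.03 on D-Arg replicate 1 and 0.195 on replicate 2. In the agmatine, putrescine and polyamine catabolism list (median -0.08, adjusted p = 0.734) aguB, for an amidohydrolase of the agmatine route, rose by 2.90 (121.3 to 324.3 and 2535). In polyamine synthesis (median -0.11, adjusted p = 0.38) the lysine decarboxylase gene ldcA (PA1818) rose by 2.05. The arginine decarboxylase gene speA was at 1.40 and did not pass. In that list 2 genes passed when adjusted over the list alone. Of the D-amino acid genes other than dau (median 0.37, adjusted p = 0.0641), dadA, the D-amino acid dehydrogenase used on D-alanine, rose by 2.30, to 1086 and 3560 from 399.8. In the fermentative arginine deiminase pathway (median 0.003, adjusted p = 0.553) arcC, for carbamate kinase, was called with a log2 fold change of 1.72. The list median was -1.37 on D-Arg replicate 1 and 1.45 on replicate 2. The signal of arcC was 230.9 without D-Arg and 162.4 and 3583 with it, so that 1 array alone carries the call and the log2 ratio on the other was -0.51. Each of these 5 lists had 1 call over all genes, and 1 when adjusted over the list alone apart from polyamine synthesis. None of gbuA, aguB, ldcA, dadA and arcC was called with median centring. The D-amino acid list was called without the filter on dim genes (adjusted p = 0.0124) and with an offset (adjusted p = 0.036), but its median was -0.35 on D-Arg replicate 1 and 1.76 on replicate 2.

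Genes that make arginine and assimilate nitrogen were lower in part. In arginine biosynthesis argF, for the anabolic ornithine carbamoyltransferase, fell from 1831 to 267 ± 38 (SD, n = 2), a log2 fold change of -2.79 ± 0.53 (SE, adjusted p = 1.76e-05), while argG was at -0.92 and carA at -0.69 and did not pass. That list had a median of -0.45 and 1 of 10 genes called, also when adjusted over the list alone (camera adjusted p = 0.0641, and 0.0347 with quantile normalization and 0.0362 without the filter, where the list was called). In nitrogen assimilation gdhA (PA4588), for the glutamate dehydrogenase of biosynthesis, fell from 415.2 to 56.0 ± 4.8 (SD, n = 2; log2 fold change -2.89, adjusted p = 2.3e-05), and the glutamate synthase genes gltB and gltD were at -1.48 and -1.31 without passing. The list median was -0.64 and 3 of 8 genes fell when adjusted over the list alone, with a camera adjusted p of 0.00347 (adjusted p = 0.713 with an estimated correlation). The list median was -1.17 on D-Arg replicate 1 and -0.20 on replicate 2. This gap came from other members, with amtB, ntrC, ntrB and glnA dimmer on replicate 1. The log2 ratios of gdhA, gltB and gltD were -2.81, -1.60 and -1.24 on replicate 1 and -2.98, -1.36 and -1.38 on replicate 2. In glutamate uptake and use (median -0.23, adjusted p = 0.868) gdhB (PA3068), for the catabolic glutamate dehydrogenase, rose by 1.89, from 1809 to 7027 ± 2948 (SD, n = 2), and 9 of 10 genes did not pass, also over the list alone. Of 19 tricarboxylic acid cycle genes 0 were called in limma (median -0.15, adjusted p = 0.868), and 0 when adjusted over the list alone. The medians of these lists changed sign between the D-Arg arrays, at 0.08 and -0.49 for glutamate uptake and use and 0.11 and -0.44 for the tricarboxylic acid cycle. With median centring neither argF, gdhA nor gdhB was called.

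**Figure D2:**
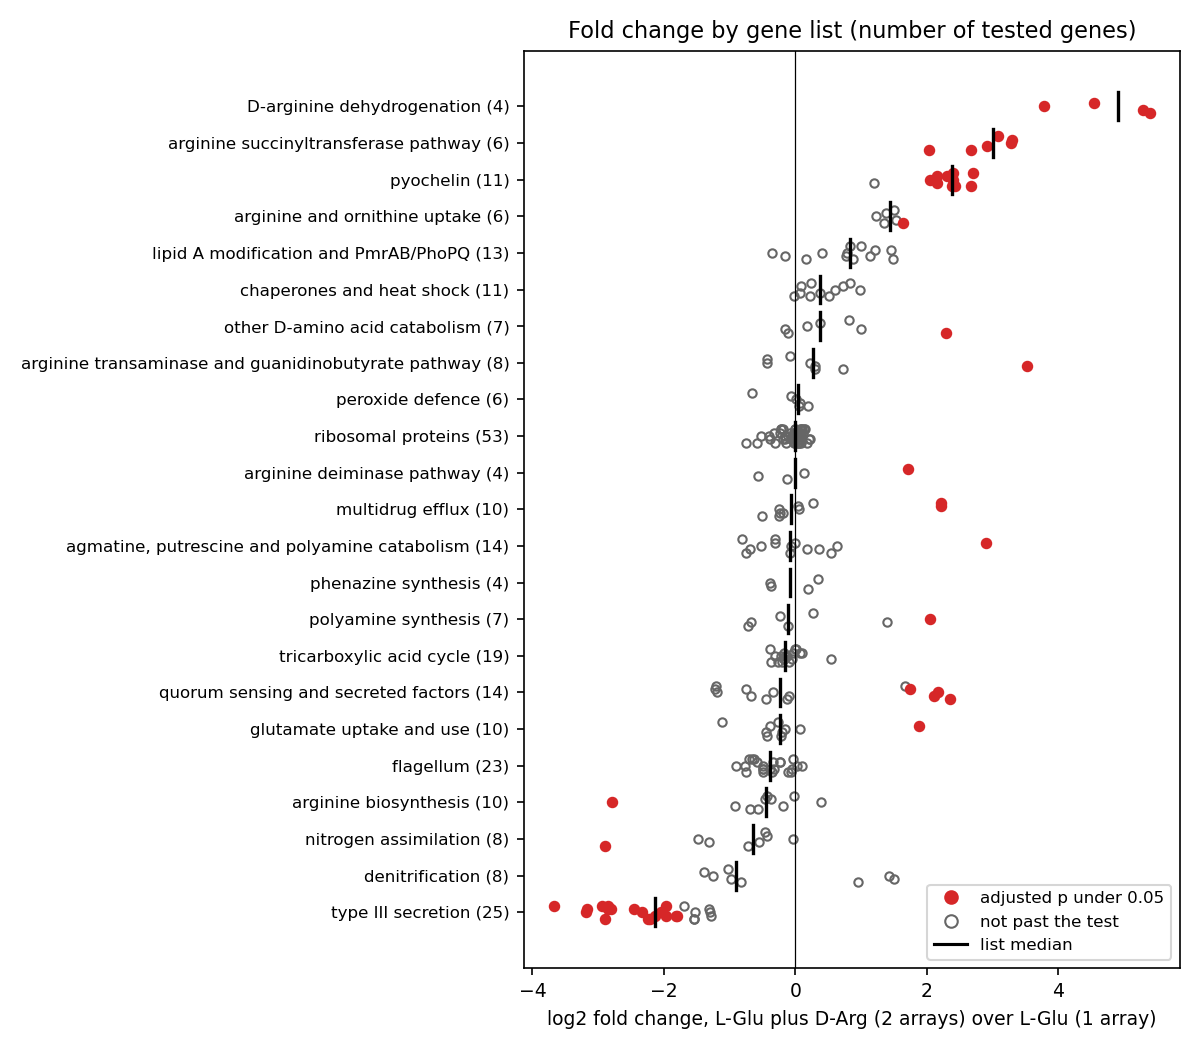
Log2 fold change of L-Glu plus D-Arg (mean of 2 arrays) over L-Glu (1 array), on the horizontal axis, for each tested member of 23 gene lists (rows, with the number of tested genes); filled points passed the test, open points did not, and bars are list medians. Medians run from -2.13 in type III secretion to 4.92 in D-arginine dehydrogenation.

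The largest increases were those of exaB, PA1981 and exaA, in a run of genes that also holds the pqq genes. The product of exaA is a quinoprotein ethanol dehydrogenase, that of exaB the cytochrome that takes its electrons, and the pqq genes make the cofactor pyrroloquinoline quinone. The signal of exaA (PA1982) went from 53.6 to 13310 and 6795 on the D-Arg arrays (log2 fold change 7.47 ± 0.53, SE; adjusted p = 1.25e-41). That of exaB (PA1983) was 14.0 on the L-Glu array, below background there, and 14480 and 6799 with D-Arg. By the mean D-Arg log2 signal it was at least 299-fold higher, with the L-Glu value raised to the L-Glu background of 33.1 (limma adjusted p = 2.16e-66). In the same run PA1981 rose by 7.67, PA1975 by 5.43, pqqB by 4.68 and the sensor kinase gene ercS' by 5.09 on the log2 scale. The L-Glu signals of PA1974 and of the response regulator gene eraR were also below background. By the same kind of mean, these genes were at least 28.9-fold and at least 9.33-fold higher with D-Arg. The D-Arg signals of PA1974 lay far apart, at 2448 and 374.5, and those of PA1975 were 3262 and 1279. Of these named genes exaA, exaB, PA1981, pqqB, ercS' and eraR were called with quantile normalization as well, with adjusted p of 0.012, 0.00996, 0.00996, 0.0422, 0.0422 and 0.0422, whereas PA1975 reached 0.06 and PA1974 0.215. With median centring PA1974 was not called either (adjusted p = 0.102).

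Type III secretion was the list that fell most: 18 of 25 tested genes fell, 25 when adjusted over the list alone, and the median log2 fold change was -2.13. The translocator gene popB (PA1708) went from 1463 to 115 ± 9.2 (SD, n = 2), a log2 fold change of -3.67 ± 0.55 (SE, adjusted p = 4.46e-09), and pcrV, for the needle tip protein, from 450.9 to 49.9 ± 2.6 (SD, n = 2), a log2 fold change of -3.18. The toxin gene exoS fell by 2.85 and PA3842, the gene of its chaperone, which the list does not hold, by 2.89 on the log2 scale. The genes popD, pcrH, PA1701 and exsB fell by 2.89, 3.16, 2.93 and 2.84. Apart from gdhA, the remaining gene of the 10 with the largest decrease, PA4912, for a predicted transporter permease, fell by 2.90. The list was called by camera (adjusted p = 7.76e-35, and adjusted p = 0.504 with an estimated correlation). With median centring 3 of these genes were called (popB, pcrV and pcrH) and with quantile normalization 0, and 14 further members of the list were too dim to be tested.

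Of 11 pyochelin genes 10 rose, with a median log2 fold change of 2.39, and all 11 when adjusted over the list alone. The synthesis gene pchB (PA4230) went from 84.9 to 559 ± 100 (SD, n = 2; log2 fold change 2.71 ± 0.55, SE; adjusted p = 5.49e-05), pchE rose by 2.68 and the receptor gene fptA by 2.44. The D-Arg arrays differed for pchE (595.1 and 208.2, against 55.0 with L-Glu), for fptA (1010 and 522.2, against 134.2) and most for pchD, which was called but had a log2 ratio of only 0.71 on replicate 2. Camera called the list (adjusted p = 6.2e-20, and adjusted p = 0.713 with an estimated correlation), and 0 of its genes were called with median centring. The other siderophore, pyoverdine, was not tested, since all 15 of its genes fell in the dimmest 25% of genes. Their highest signals on the arrays were 66.3, 99.6 and 52.5, above background. Of the haem uptake and other iron-repressed genes only tonB1 and PA4709 passed the filter, and neither was called (median 0.28). With D-Arg tonB1 was at 966.7 and 226.1, against 452 with L-Glu, and PA4709 at 195.1 and 94.0, against 95.4. In the lipid A modification and PmrAB/PhoPQ list, whose genes alter the cell surface, the median was 0.83 and 0 of 13 genes passed in limma (2 when adjusted over the list alone), with oprH at 1.49 and arnB at 1.45. Camera gave an adjusted p of 0.0021 (adjusted p = 0.713 with an estimated correlation).

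The genes pqsA, pqsB, pqsC and pqsD, for the quinolone signal, rose by 2.35, 2.12, 2.17 and 1.74, and were the 4 called of 14 in the quorum sensing list, 5 when adjusted over the list alone. Their log2 ratios were 1.46, 1.76, 1.66 and 1.16 on D-Arg replicate 1 and 3.25, 2.48, 2.68 and 2.32 on replicate 2. The neighbouring pqsE was at 1.67 and did not pass over all genes, with log2 ratios of 1.13 and 2.20 on these arrays. The remaining members of that list lay lower: its median was -0.23 and its mean 0.29, of opposite sign (adjusted p = 0.232). In multidrug efflux PA2019 and PA2018, which encode the pump proteins MexX and MexY, rose by 2.22 and 2.22. The other 8 genes did not pass, and the list median was -0.07 and its mean 0.34 (adjusted p = 0.232; 2 genes when adjusted over the list alone). With median centring neither the pqs genes nor these pump genes were called. In limma 0 genes passed in each of the lists flagellum (23 genes, median -0.39, adjusted p = 0.0992), denitrification (8, -0.90, adjusted p = 0.734), phenazine synthesis (4, -0.08, adjusted p = 0.999), chaperones and heat shock (11, 0.38, adjusted p = 0.101), peroxide defence (6, 0.04, adjusted p = 0.996) and ribosomal proteins (53, 0.003, adjusted p = 0.996). Adjusted over the list alone, 2 denitrification genes were higher and 2 lower, and the others of these lists again gave 0. The higher ones were narK2 and narK1, for which D-Arg replicate 2 alone carries the change: narK2 read 42.1 with L-Glu and 39.3 and 365.1 with D-Arg, and narK1 66.0, 70.9 and 445.4. The denitrification median was -0.96 on replicate 1 and -0.16 on replicate 2. On these 2 arrays the chaperone median was 0.51 and 0.64. The median changed sign between them in phenazine synthesis (0.34 and -0.29), peroxide defence (0.10 and -0.06) and ribosomal proteins (0.22 and -0.15). With quantile normalization the ribosomal list was called with a median of -0.15 (adjusted p = 0.00287), the flagellum list with -0.40 (adjusted p = 0.0267) and the chaperone list with 0.41 (adjusted p = 0.0267). Without the filter on dim genes the denitrification median was 0.79, of the other sign.

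Between the D-Arg arrays themselves, genes of arginine fermentation and the flagellum and the single gene dctA stood apart. The signal of the dicarboxylate transporter gene dctA was 56.4 on replicate 1 and 3266 on replicate 2 (77.8 on the L-Glu array), that of arcC 162.4 and 3583, and that of arcB 765.1 and 10810. Of these dctA, like arcC, was among the 121 genes called higher, with a log2 fold change of 2.46 that rests on replicate 2 alone. The differences of dctA, arcC and arcB were the largest of single genes, and the genes and lists singled out here were chosen after their values were seen. The 4 arginine deiminase genes were all brighter on replicate 2, by a median of 3.35 on the log2 scale, and 22 of 23 flagellum genes were, with a list median of 0.98. The central 95% of 10000 random lists of like signal ran from -0.71 to 0.46 and from -0.25 to 0.33. Random lists hold unlinked genes, whereas neighbouring genes tend to move together, so that these ranges are likely too narrow. Also outside the range of random lists were other D-amino acid catabolism (median 1.71), denitrification (1.35) and nitrogen assimilation (0.50), brighter on replicate 2, and glutamate uptake and use (-0.76), polyamine synthesis (-0.58) and the tricarboxylic acid cycle (-0.47), dimmer there. The genes of the dau, aru and type III secretion lists differed less, with medians of -0.43, -0.17 and -0.08, inside the range of random lists. The pyochelin median of -0.37 was inside that range too, although all 11 of its genes were dimmer on replicate 2. In all, 544 of 4158 genes (13.1%) were at least 2-fold apart between the D-Arg arrays, against 584 between L-Glu and replicate 1 and 570 between L-Glu and replicate 2. The Pearson correlation of log2 signals across tested genes was 0.903, 0.862 and 0.861. With 1 array against 1 there is no test of these differences. The series describes its experiments as independent but no label says that the D-Arg arrays came from separate cultures, and all p-values measure only the spread between these arrays, which may be technical.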

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

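The size rule in this part was fixed for genes before the data were examined, and its use on intergenic probe sets was chosen afterwards. Intergenic probe sets take no part in the comparison of genes. Of these, 7 of 199 were at least 2-fold higher on both D-Arg arrays than on the L-Glu array and above background there, and 1 was lower. Without the condition on background the counts were 13 and 6. Among 4158 tested genes the 2-fold rule alone gave 158 higher and 118 lower, and simulations without any effect gave means of 99.8 and 99.5. No such simulation covers intergenic probe sets, so that their counts do not show that the groups differed. These counts were not tested beyond the size rule, and no explanation was weighed.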

How the results depend on the processing

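The fits with exchanged prior degrees of freedom were chosen after the data were seen; all other settings were fixed before. The counts of called genes fell most with quantile normalization and median centring, where the prior degrees of freedom were 4.22 and 5.56, against infinite as reported. Quantile normalization called 11 genes higher and 0 lower (289 at an unadjusted p under 0.05), and median centring 30 and 3. The reported values with the prior degrees of freedom of the quantile fit gave 2 and 0, whereas quantile-normalized values with infinite ones gave 168 and 91. For quantile normalization the prior degrees of freedom and not the scaled values thus account for most of the loss. For median centring they were not exchanged, and the cause of its loss was not tested. All 11 calls with quantile normalization and all 33 with median centring were among the 178. Without the dimmest 40% of genes 34 genes fell, which tests fewer genes, and 73 were at least 2-fold lower on both D-Arg arrays. With an offset before log2 70 were at least 2-fold lower and 305 at least 2-fold apart between the D-Arg arrays, since an offset shrinks the ratios of dim genes, and without a filter, which adds dim genes, 847 were apart. A 3-fold rule gave 94 higher, 47 lower and 158 apart. With only 1 D-Arg array, 284 to 296 genes were at least 2-fold higher and 286 to 288 lower. Of the lists, 7 were called as reported, 0 with an estimated correlation, 0 with fry and 11 with quantile normalization; the cause of the last was not tested. Of the 41 called named genes 40 kept their sign under every setting, and arcC ranged from -0.51 to 3.96 with 1 D-Arg array left out. That count is no evidence of robustness. Many of these genes were picked for a 2-fold change the same way on both D-Arg arrays, which fixes their sign with either left out. Of these 41, 24 lost their call with median centring, 32 with quantile normalization, 3 without the intensity trend, 2 without a filter, 2 of those still tested without the dimmest 40%, and 0 with robust eBayes or an offset. No paired analysis was possible because the L-Glu group has 1 array, so that the groups share fewer than 2 replicate numbers. The filter left 1387 dim genes untested, among them all pyoverdine genes, although many such genes lay above background.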

Other observations

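Of the tests in this part, that of dim probe sets for the D-Arg arrays was chosen after its result was seen; the runs of neighbours and the held-out lists were sought after the largest changes had been seen, with each test set before its own result. A scan of the gene order in 2 passes found 16 runs of neighbouring genes that moved together, 10 higher and 6 lower with D-Arg, with 104 of the 178 called genes. The threshold for the window mean of log2 fold changes, less their median, was 2.56 in the first pass and 1.48 in the last. The runs aotP to aruE, PA1700 to PA1711, PA1970 to PA1991, algD to arnB and dauB to PA3865 came from the first pass. All others passed only the lower threshold. Of the 16 runs, 8 with 55 called genes hold members of the fixed lists, among them the dau, aru, pyochelin and type III secretion genes already described. The other 8 runs (4 higher, 4 lower) hold 49. The run from PA1970 to PA1991, with the exa and pqq genes, had 17 of 20 genes called higher and a median log2 fold change of 4.43, and 12 of them passed with median centring and 8 with quantile normalization. In the run from algD to arnB, which holds the operon for the exopolysaccharide alginate, 9 of 10 genes were higher with a median of 2.83, and 4 of these (algD, algG, algF and algA) passed with median centring, and 0 of them in limma with quantile normalization. The run from PA3515 to PA3523 had 6 of 9 genes called higher (median 1.78), but its median log2 ratio was 2.23 on D-Arg replicate 1 and 0.849 on replicate 2, and 0 of its genes were called in limma with median centring or quantile normalization.

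Runs that were lower with D-Arg included coxB to PA0110, with genes of the aa3-type terminal oxidase, in which 5 of 6 genes were called with a median of -1.99. The run from pprA to pctC, which holds the tad and rcp genes for assembly of Flp pili, had 7 of 12 genes called and a median of -1.96. In PA4908 to PA4913, around a predicted amino acid transporter, 5 of 6 genes were called lower (median -1.83), and in PA2363 to PA2373, a cluster of type VI secretion genes, 5 of 10 (median -1.73). With median centring and with quantile normalization 0 genes of these 4 runs were called in limma.

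Independent noise of single probe sets would not move neighbours together, and the rank correlation of fold changes between neighbouring tested genes was 0.403, against at most 0.0405 in 1000 random gene orders. Noise of dim probe sets would need genes near background. The median over genes of the runs of the highest of the 3 signals was 720, against a background of 46.2. Many of these genes were thus bright on at least 1 array. That cannot exclude such noise, because the filter had left out dim genes and the highest signal passes over the dimmer side of a ratio. On the L-Glu array exaB, eraR and PA1974 were below background. Also open is whether the runs answer D-Arg or may be peculiar to the single L-Glu culture. The number of L-Glu arrays was 1, and no second one shows how such cultures vary. Of the 3 ways to set 1 array against the others the real one called 178 genes and the highest other 0 (1 way with as many, the real one itself), and 3 ways are too few for a share under 0.05. The other ways had prior degrees of freedom of 2.74 and 2.92, and with infinite ones they called 253 and 291 genes.

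The D-Arg arrays differed from each other in 544 genes by at least 2-fold. Noise of dim probe sets would leave few such genes among bright ones, but 11.1% of the brightest 25% of tested genes were 2-fold apart (115 of 1040, 95% exact interval 9.22 to 13.1, counting error only). A candidate explanation is less oxygen in the culture of replicate 2: 12 held-out low-oxygen genes had a median difference of 0.419 on the log2 scale, above the central 95% of random lists (-0.45 to 0.259), although 5 of the 12 were lower there. Another is less available sulphur in the culture of replicate 1: all 11 tested held-out sulphur-supply genes were brighter on replicate 1, with a median difference (replicate 2 minus replicate 1) of -0.969 (random lists -0.43 to 0.41). The random lists again hold unlinked genes, so that their ranges may be too narrow for lists with neighbouring genes. Both explanations may hold at once, neither was measured directly, and growth stage at harvest stays open as untested.

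The tRNA probe sets were dimmer on D-Arg replicate 1: 16 of 18 were below replicate 2 (median difference 1.21 on the log2 scale) and 16 below L-Glu (median -1.12). Loss of short RNA during preparation is a possible explanation, and 5S rRNA, which is short too, was lower there relative to 16S and 23S rRNA by 0.487. The 416 shortest protein genes, with a coding length of at most 360 bases, were lower on replicate 1 than the rest by a median of only 0.143 (95% interval 0.0679 to 0.241). The whole interval lay under the bound set beforehand, so that by its own rule the test went against the loss. That bound was later held to be too high to decide. Coding length is not transcript length in operons and such messages are far longer than tRNA, and so the loss remains open. No biological explanation was tested.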
